A study of Homo sapiens with 5 samples.

How the data were processed

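Poly(A)-selected RNA was sequenced from COLO 320DM cells, a human colorectal adenocarcinoma line, in 5 libraries, each labelled with a different siRNA. Per the labels' protocols, RNA was extracted with TRIzol and an RNeasy column and libraries were made with the KAPA RNA HyperPrep kit. The siIDT, sino4 and siSMPLT libraries formed the USP17 siRNA group (replicates 1, 2 and 3), and the siL2 and siNT libraries formed the control siRNA group (replicates 1 and 2). The series names siNT and L2 as its non-silencing controls, and the other libraries were taken as the USP17-targeting ones by elimination. Replicate numbers follow the order of the samples and pair nothing. Each duplex had 1 library and no label states separate cultures, so p-values measure only the spread between these libraries, which may be technical and includes effects of each duplex's own sequence.

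Per the submitters' processing notes, base calls were converted with bcl2fastq 2.20, reads were aligned to GRCh38 with STAR 2.7.1a, and expression was estimated with RSEM 1.3.2. The annotation release, the read layout and the strand setting are not given in the sources used here. The deposited read count tables have STAR's layout, with whole-number counts per gene without regard to strand, on the gene's strand and on the opposite strand. The deposited RSEM tables hold expected counts, in which reads that map to several places are shared out, and TPM, which the authors computed with RSEM. Each file listed 60651 genes. The column for the gene's own strand held 18.7 to 19.9 times the reads of the opposite one and was used throughout. The rows for unmapped, multi-mapping, ambiguous and unannotated reads made up 22.8% to 24.4% of all reads and were left out of library sizes and tests. STAR's counts leave out reads that map to several places, which affects families of near-identical genes most.

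Reads in genes numbered 31704821 to 36276143 per library. A count of 0 allows up to 3 reads, or 0.0827 to 0.0946 CPM (reads scaled to library size), and this limit covers counting error only. Symbols were found for 42023 of the gene identifiers. Coordinates and untranslated regions came from GENCODE release 29 on GRCh38, which lists 58405 of them.

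Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, libraries were scaled by TMM, and the groups were compared with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are USP17 siRNA over control siRNA. On simulated data with 3 and 2 libraries and 16341 genes, 50.7% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered. In those simulations 41 of 485 calls (8.5%) were false, above the nominal 5%. Gene lists, 28 in number and fixed before the data were examined, were compared with all other tested genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01. Lists with fewer than 5 tested members were described only. Of 579 genes on the lists, 576 matched a gene identifier.

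Further descriptive measures were fixed in advance. Concordant genes had log2 CPM (prior count 2) at least 1.5-fold beyond both controls in each of the 3 USP17 libraries. Fold changes of pairs of duplexes were correlated across genes, beside 20 simulations of unchanged groups. Library pairs were compared by the number of genes 1.5-fold or more apart. Genes named in the text were the 12 with the largest change in each direction among those past the threshold with a log2 CPM of at least 1 and no overlap between groups, then CTNNB1, MYC, AXIN2, LGR5, CCND1, CDC25A and the USP17L family whatever their values, and up to 3 members per list with the smallest p. Genes named outside this rule were chosen after their values were seen, and 1 gene under the rule is not reported here.

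The 3' UTR scan asked, for 16163 sequences of 7 bases (7-mers), whether the 10800 coding genes searched differed in fold change according to whether their 3' UTR held the 7-mer, with UTR length, GC content and expression as covariates and CPM offset by 0.1 before taking logs. It was run in Python 3.11.15 with scipy 1.17.1, and it recovered a planted 7-mer. Carriers left out of genes and lists were taken from all tested genes with an annotated 3' UTR. To see whether the deposited expected counts kept multi-mapping reads, genes with 0 read counts and at least 50 RSEM reads were searched for 50-mers in other annotated loci. Alternatives were DESeq2's size factors and its Wald test (DESeq2 1.42.0), limma-voom, other filters, RSEM expected counts rounded to whole numbers, the unstranded column, other thresholds and leaving out each library.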

Results

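The data were gene-level read counts from 5 libraries of COLO 320DM, a colorectal adenocarcinoma line that carries an amplified MYC locus. The series asks how USP17, a deubiquitinase, acts in colorectal cancer and links it to beta-catenin. In the group of 3 libraries each was labelled with a different USP17-targeting siRNA (siIDT, sino4 or siSMPLT), and in the group of 2 with a control siRNA (siL2 or siNT). Reads in genes came to 32259474, 32211160 and 31704821 in the siIDT, sino4 and siSMPLT libraries and to 34320214 and 36276143 in siL2 and siNT. Reads that fell on no gene's own strand were 7.15%, 7.05% and 7.49% of all reads in the siIDT, sino4 and siSMPLT libraries and 6.58% and 6.37% in siL2 and siNT, with no overlap between the groups.

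No read was counted on the targeted genes in any library. USP17 is encoded by the USP17L family of near-identical intronless genes, with 30 members in the annotation on chromosomes 4 and 8. All 30 had 0 reads on their own strand, 0 RSEM expected counts and a TPM of 0 in all 5 libraries, controls included. A single read lay on the opposite strand of 1 member in the siSMPLT library. In 21 members a median of 3.5% of 50-base stretches lay in at most 4 copies, so reads from them can be lost as multi-mapped. In USP17L7, USP17L10 and USP17L2, 64.1%, 45.6% and 35.4% of such stretches occur in no other annotated gene. These members had 0 reads too, controls included. Whether the siRNAs lowered the family could not be measured from these counts. No fold was given, since both groups were at 0.

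CTNNB1, which encodes beta-catenin, was lower with all 3 USP17 siRNAs. It measured 198, 200.3 and 200.5 CPM against 355 and 326 CPM in the controls, or 199.5 ± 1.55 (SD, n = 3) against 340.6 ± 20.3 (SD, n = 2). Its log2 fold change was -0.77 ± 0.07 (SE), with an adjusted p of 0.00215 in edgeR's quasi-likelihood test. The gene lies on chromosome 3 from 41194741 to 41260096 (GRCh38), and its 3' UTR of 1111 bases holds, at base 777, the 7-mer ATCACTC. In each USP17 library its 884 carriers were lower than other genes by 0.14 to 0.23 on the log2 scale, given the scan's covariates. The carriers' own median log2 fold changes were -0.15, -0.122 and -0.089 in siIDT, sino4 and siSMPLT. AXIN2, a feedback inhibitor and direct target of beta-catenin, fell by 0.57 on the log2 scale, from 345.1 to 232.5 CPM (adjusted p 0.00416, edgeR). TNFRSF19, another Wnt target, fell from 114 to 46.4 CPM (log2 fold change -1.30), and LGR5, an intestinal stem cell receptor, from 11.6 to 5.59 CPM (-1.06). MYC stood at 3266 ± 57.1 CPM (SD, n = 3) against 3917 ± 421 CPM (SD, n = 2), a log2 fold change of -0.26 with an adjusted p of 0.0519 in edgeR's test. It passed with DESeq2's Wald test (adjusted p 0.0392), limma-voom (0.0494), DESeq2's size factors (0.0489) and without siL2 (0.00376). CCND1 had a log2 fold change of 0.14 and CDC25A, a reported USP17 substrate, of 0.03, both within the spread between libraries. JUP, which encodes plakoglobin, the close relative of beta-catenin, rose by 0.44, and CTNNA1, the alpha-catenin gene, had a log2 fold change of -0.62 that was past the threshold. The 3' UTRs of LGR5 and CTNNA1 hold TCACTCA, which shares the bases TCACTC with ATCACTC. Carriers of TCACTCA were shifted by -0.203, -0.121 and -0.082 in siIDT, sino4 and siSMPLT. AXIN2 and TNFRSF19 hold neither 7-mer. These carriers were looked up after the data were seen. LGR5 lost its call without siIDT (adjusted p 0.0807, edgeR) and without sino4 (0.097), as JUP did (0.0636 and 0.0827). CTNNA1 lost its call in 7 alternatives, among them leaving out either control and RSEM counts (adjusted p 0.0623, edgeR).

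**Figure D1:**
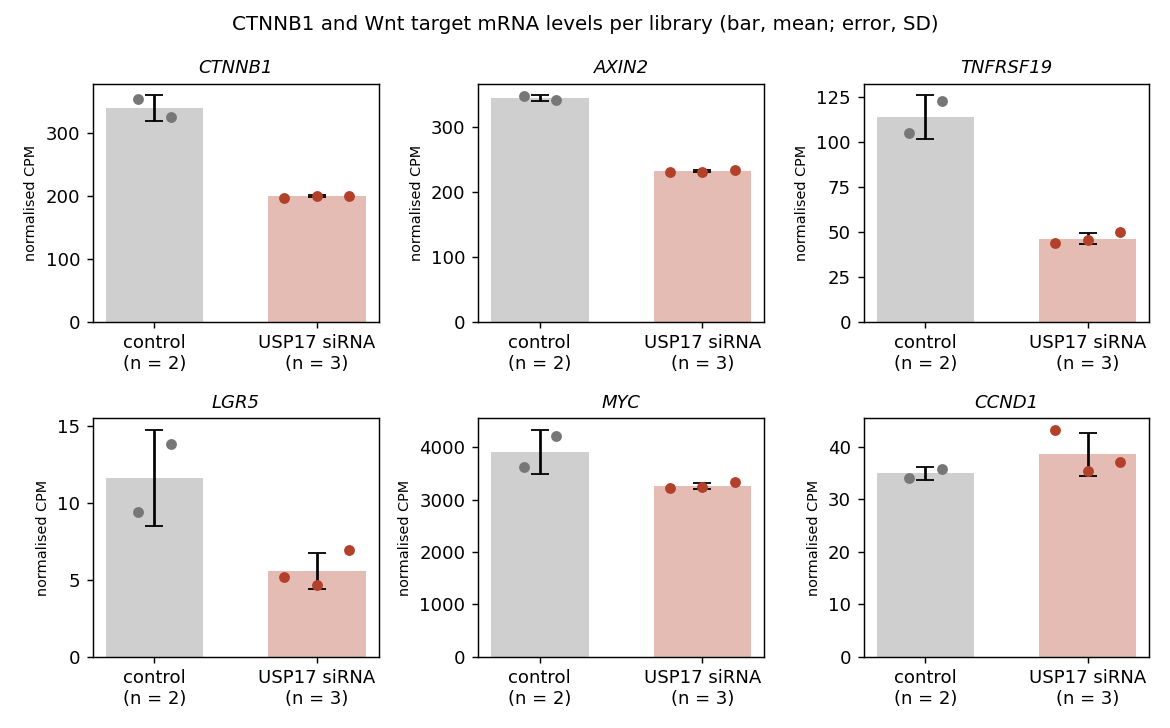
Normalised CPM of 6 genes in each library, with points for libraries, bars for group means and error bars for SD (control siRNA, n = 2; USP17 siRNA, n = 3); each axis starts at 0. CTNNB1 was at 198 to 200.5 CPM in the USP17 libraries and at 326 to 355 CPM in the controls, while the groups overlapped for CCND1.

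Across the transcriptome, 1710 of 16341 genes tested passed an adjusted p of 0.05 in edgeR's test, 759 higher and 951 lower with USP17 siRNA. Most changes were small, with a median absolute log2 fold change of 0.53, and 134 genes were higher and 87 lower by at least 2-fold. Among called genes with a log2 CPM of at least 1, the largest rises were in TMEM108-AS1 (log2 fold change 3.56), PDE5A (2.57), a cGMP phosphodiesterase, TNMD (2.51), SRD5A2 (2.18), a steroid 5-alpha-reductase, and IFI44 (2.01). Also higher were COL9A1 (1.94), KNG1 (1.94), COL24A1 (1.93), HOXA9 (1.70), PTGFR (1.67), MACROD2 (1.64) and HNF4G (1.60). The largest falls at that level were in SMCO1 (-3.40), CHAC1 (-2.68), a glutathione-degrading enzyme, STX11 (-1.97), JDP2 (-1.69), SLC13A1 (-1.67) and the zinc transporter SLC39A6 (-1.53). CIAO2B (-1.49), PROX1 (-1.39), SLC7A11-AS1 (-1.37), SORBS2 (-1.34) and ETV5 (-1.32) followed, of which PROX1 lost its call with RSEM counts (adjusted p 0.0518, edgeR) and with limma-voom (0.0512). CHAC1 and SMCO1 differed widely between the controls, at 3.12 and 14.1 CPM and at 15.7 and 5.12 CPM in siL2 and siNT. Of genes searched for ATCACTC, 20.4% of those called lower held it, and 38.0% of those lower by at least 2-fold. The share was 8.0% of those called higher and 8.2% of all searched. JDP2, CIAO2B and PROX1 held it among the falls named here, as did KNG1 and HNF4G among the rises. SMCO1, CHAC1, JDP2 and CIAO2B held TCACTCA, and none of the named rises searched did. STX11, SLC13A1, SLC39A6, SORBS2 and ETV5 held neither 7-mer. These shares and carriers were taken after the data were seen. Because both 7-mers were picked for the fall of their carriers, some of the excess is built in. All 1710 called genes had no overlap between the groups; 45.9% of tested genes had none, against 20% by chance. The count fell to 349 without siIDT, 130 without sino4 and 1041 without siSMPLT, and was 2633 without siNT.

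Of 22 Wnt/beta-catenin targets tested, 7 fell and none rose (10 fell and 1 rose adjusted over the list alone). Besides AXIN2, TNFRSF19 and LGR5 these were FGF20, PROX1 and the feedback regulators NKD1 and ZNRF3. The list was lower than other genes by camera (adjusted p = 6.45e-06; adjusted p = 0.411 with an estimated correlation). The 12 members without any of the 6 7-mers that marked lower genes in a USP17 library, 2 of them called, did not pass (mean log2 fold change -0.11, camera adjusted p = 0.15; 0.705 with an estimated correlation). This test was chosen after the data were seen, on 7-mers picked for the fall of their carriers in these libraries. The list of endoplasmic reticulum chaperones and unfolded protein response genes fell most uniformly, with 12 of 16 lower and none higher (13 adjusted over the list alone). Its camera adjusted p was 1.89e-09, or 0.411 with an estimated correlation. HYOU1 fell by 0.98, HERPUD1 by 0.69 and XBP1, a transcription factor of the unfolded protein response, by 0.49. HYOU1 holds ATCACTC, while HERPUD1 and XBP1 do not. Targets of ATF4, the amino acid stress factor, had 8 of 22 lower (17 adjusted over the list alone; camera adjusted p = 2.94e-09; 0.814 with an estimated correlation). SLC7A5, an amino acid transporter, fell from 425.6 to 217.1 CPM and MTHFD2 from 721.1 to 418.2 CPM. The siNT library stood apart across this list: its median lay 1.04 above the USP17 mean on the log2 scale, against 0.21 in siL2, and it was the farther control for all 22 members. Without siNT the list's mean log2 fold change was -0.26 in place of -0.81 (camera adjusted p = 0.00218). Cholesterol synthesis had 8 of 24 lower (14 adjusted over the list alone), among them HMGCS1 (-0.39), SQLE (-0.40) and LSS (-0.41), with a camera adjusted p = 1.03e-05 and 0.411 with an estimated correlation. LSS holds ATCACTC, while HMGCS1 and SQLE do not.

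Smaller shifts passed camera in 4 further lists. Proteasome subunits had 3 of 27 lower (7 adjusted over the list alone; PSMB2, PSMB7 and PSMB4; camera adjusted p = 0.0016; 0.823 with an estimated correlation). MYC targets of ribosome biogenesis had 4 of 30 lower (4 adjusted over the list alone), led by ODC1 (-1.03), which makes polyamines (camera adjusted p = 0.00226; 0.63 with an estimated correlation). The 8q24 amplicon around MYC had 2 of 9 lower (3 adjusted over the list alone), LRATD2 (-0.51) and POU5F1B (-0.51), and its list call (camera adjusted p = 0.0304; 0.823 with an estimated correlation) was lost without siIDT, without sino4 or without siNT. The RNA interference machinery was the single list that was higher, with 4 of 12 members, TNRC6C (0.97), AGO4 (0.82), AGO1 (0.56) and TNRC6A, up (camera adjusted p = 0.023; 0.411 with an estimated correlation). Its median was 0.08, and adjusted over the list alone 4 were higher and 1, AGO2 (-0.28), lower.

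The other 17 tested lists did not pass camera (adjusted p 0.0967 to 0.871). Of 20 interferon-stimulated genes IFI44 rose, while IFI6 (-0.81) and IFITM3 (-0.41) fell (camera adjusted p = 0.863). Among G1/S genes RRM2 (0.82) and CCNE2 (1.19) rose, and among G2/M genes CCNA2 fell by 0.95 and MKI67 rose by 0.52. The controls lay on opposite sides of the USP17 mean across the G2/M list, at log2 medians of -0.25 in siL2 and 0.10 in siNT. Across the histone list they lay at 0.37 and -0.67, so the group means of both lists average over a difference between the controls. BMF (1.20) and BCL2L11 (0.63), which encode proapoptotic BH3 proteins, rose; the apoptosis list's median was -0.15 while its test pointed up. Of the reported USP17 substrates, EZH2 (0.38) alone was called, at the level of mRNA, which does not show what happened to the proteins. The colon marker CDH17 rose by 0.88 and CDX2 fell by 0.31, and ZEB1 (-0.63) and VIM (-0.31) fell among mesenchymal markers. Of the genes named in this paragraph, CCNA2, IFI6 and ZEB1 hold ATCACTC. No member of the p53, neuroendocrine, histone, ribosomal protein or mitochondrially encoded lists was called. Among lists too small to test, the nuclear RNAs NEAT1 (0.65) and MALAT1 (0.46) rose, in the libraries that also had the higher share of reads on no gene (7.05% to 7.49% against 6.37% and 6.58%), and the leukocyte marker PTPRC stood at 46.3 against 46.7 CPM.

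**Figure D2:**
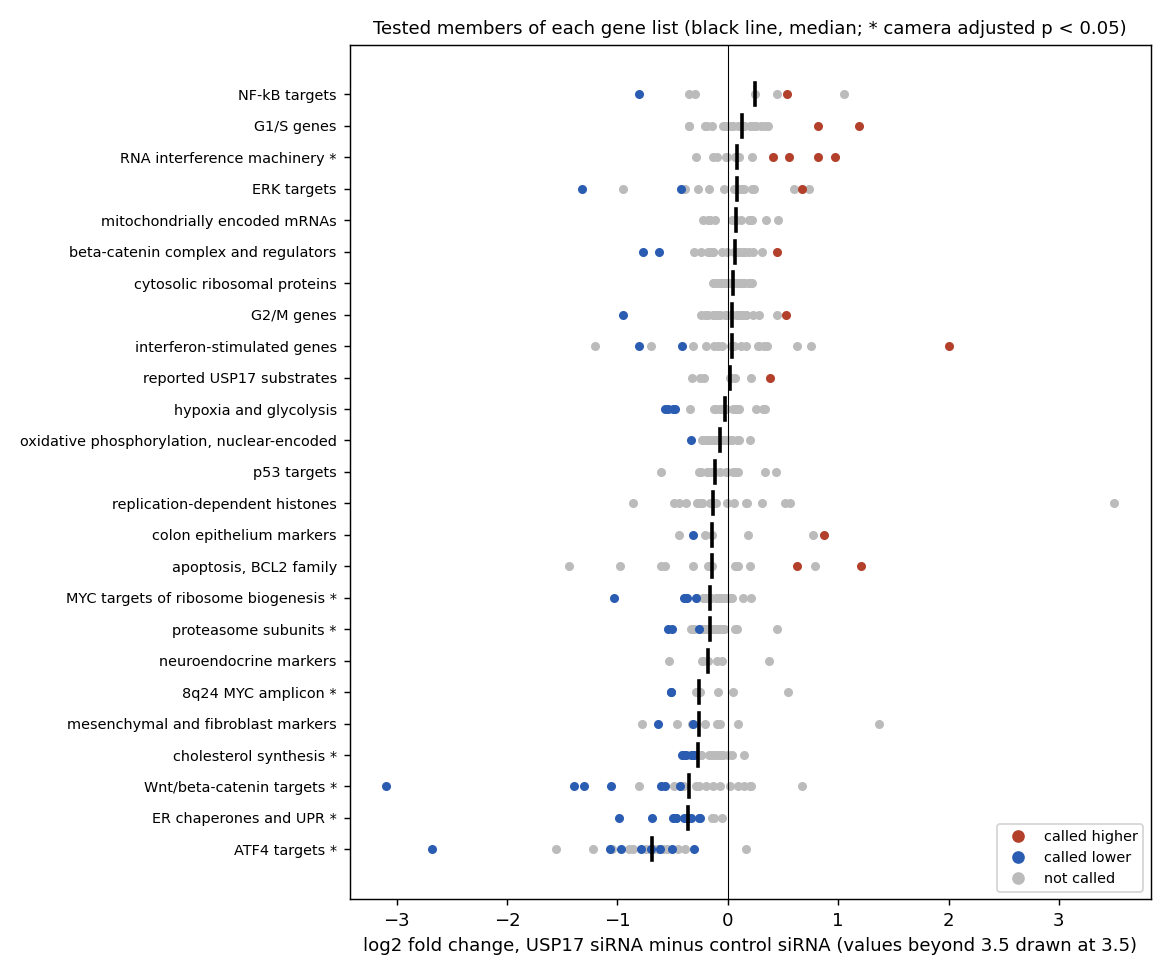
Log2 fold changes (USP17 siRNA over control siRNA) of the tested members of 25 gene lists, 1 point per gene, coloured by edgeR's call at an adjusted p of 0.05; black lines mark medians and stars mark lists past camera with the preset correlation. ATF4 targets have the lowest median (-0.69), a list in which siNT lay 1.04 and siL2 0.21 above the USP17 mean at the median.

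By fold size alone, 367 genes lay at least 1.5-fold beyond both controls in every USP17 library, 215 higher and 152 lower, and 297 of them were also called by edgeR. The other 9 splits of the libraries gave at most 70. Each of them mixes the groups, so any difference between the groups, whatever its cause, lowers their counts. Fold changes of pairs of duplexes correlated across genes at Pearson r 0.769 (siIDT and sino4), 0.696 (siIDT and siSMPLT) and 0.743 (sino4 and siSMPLT), with Spearman rho of 0.766, 0.69 and 0.736. Genes are not independent replicates, and shared controls alone gave 0.322 to 0.329 in simulation. Covariances were 0.121 to 0.146, against 0.029 simulated. The simulation gave every library the same spread for a gene. In the data the SD of log2 differences was 0.414 between the controls and 0.292 to 0.333 between USP17 libraries. The simulated values with shared controls are therefore likely too low, and the excess over them is overstated. With a different control for each duplex, r was 0.31 to 0.464, against about 0 simulated. All 3 USP17 libraries also shared the shift of ATCACTC carriers, and the siRNA sequences are not given in the sources used here. The duplexes were therefore not shown to act independently. Each was also set against the other USP17 libraries. Carriers of TCACTCA, which shares the bases TCACTC with ATCACTC, were then shifted by -0.102 in siIDT. The first-ranked sequences were TCCCCAA in sino4 (-0.016) and GTGTGCC in siSMPLT (-0.052), and no shift in these libraries reached 0.1. Agreement of the 3 libraries was thus not shown to be that of 3 distinct siRNAs. Without the ATCACTC carriers, left out after the data were seen, 311 genes lay beyond both controls and r was 0.686 to 0.758.

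The controls differed from each other in more genes than the USP17 libraries did. In siL2 and siNT 2112 genes were at least 1.5-fold apart and 597 at least 2-fold, against 1016 to 1300 and 215 to 301 genes in pairs of USP17 libraries. MYC measured 3619 and 4214 CPM in siL2 and siNT, and CTNNB1 355 and 326 CPM. In siL2 against the USP17 libraries, the 725 genes whose 3' UTR holds the 7-mer GATCATC had a log2 shift of -0.22 relative to other genes. This 7-mer also occurs in 28 of the 30 USP17L copies. In the USP17L2 transcript it starts at base 867, and ATCACTC, the 7-mer of the USP17 libraries, at base 871, so that the 2 overlap. That siL2 spares USP17 could not be checked, since no sequence is given and no library had USP17L reads, and every fold is relative to it. Without siL2 the log2 fold change of CTNNB1 was -0.71. No pair of libraries was alike within sampling noise, the lowest chi-square per degree of freedom being 5.91 (sino4 and siSMPLT).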

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

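All alternatives but those on 7-mer carriers and the opposite strand were chosen before the data were examined. CTNNB1 kept its direction and its call in every alternative that held the gene (log2 fold change -0.71 to -0.83 when 1 library was left out). Of 1710 called genes, 1690 were shared with DESeq2's size factors, 1635 of 2242 calls with DESeq2's Wald test, 1629 of 1676 with limma-voom and 1431 of 1559 with RSEM counts. Leaving out 1 library gave 130 to 2633 genes: 349 without siIDT, 130 without sino4, 1041 without siSMPLT, 2430 without siL2 and 2633 without siNT, where a lone control is assumed to vary like the USP17 libraries. An adjusted p of 0.10 gave 3074. Lists passing numbered 7 to 13 when 1 library was left out, the highest without siL2, and 0 both with an estimated correlation and with fry, where the Wnt list's mean of -0.46 had adjusted p 0.411 and 0.0544. Without carriers of ATCACTC, 1359 genes and 9 lists passed. Without carriers of any of the 6 7-mers that marked lower genes in a USP17 library, which leaves 3606 genes out, 842 genes and 7 lists passed, and the Wnt list did not (mean -0.109, camera adjusted p 0.15). Those 842 were 428 higher and 414 lower, so the excess of lower genes was gone. Part of that is built in, since the 7-mers were picked for the fall of their carriers. The USP17L family had 0 reads by RSEM and 1 on the opposite strand. Concordant genes numbered 1328 at the looser fold threshold and 79 at 2-fold. Controls were 1.5-fold apart in 181 genes and 2-fold in 26 at a log2 CPM of at least 5, and 2-fold in 395 with prior count 5. The correlations for siIDT and sino4, siIDT and siSMPLT, and sino4 and siSMPLT were 0.929, 0.841 and 0.907 at a log2 CPM of at least 5, 0.699, 0.612 and 0.659 with RSEM, and with different controls 0.464, 0.42 and 0.419 or, exchanged, 0.426, 0.31 and 0.344. Among uncalled genes the sign turned when 1 library was left out for CDC25A (-0.005 to 0.063), PTPRC (-0.158 to 0.153) and LYZ (-0.076 to 0.364), and with RSEM for H4C14 (-0.068), which had 0 reads in both controls. Of the other named genes, 39 lost their call without siIDT, 48 without sino4 and 11 without siSMPLT. Except where fewer libraries or a changed threshold account for it, the cause was not tested.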

Other observations

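The 7 gene families in this paragraph were chosen after the called genes were seen, so their counts are not independent evidence. HOX genes, which encode positional transcription factors, were higher in 13 of 34 tested and lower in 1, against 643 higher and 905 lower of 12539 coding genes (median log2 fold change 0.39; camera adjusted p 9.43e-09; 0.0828 with an estimated correlation). HOXA9 (1.70), HOXC9 (1.27), HOXA5 (1.31) and HOXC11 (0.69) were among them, and HOXB9 (-1.80) was the exception. At the median siNT lay at -0.63 and siL2 at -0.24 from the USP17 mean over the family, on the log2 scale. ZNF zinc finger genes were higher in 41 of 417 and lower in 5 (median 0.19; camera adjusted p 9.11e-08; 0.104 with an estimated correlation). The TMED cargo receptors of the early secretory pathway were lower in 5 of 9 and higher in 0 (TMED9 -0.68; camera adjusted p 0.00203; 0.0828 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases were lower in 4 of 17 (camera adjusted p 2.75e-05; 0.137 with an estimated correlation). There too siNT stood apart, at a median of 0.50 above the USP17 mean on the log2 scale against 0.13 in siL2, as for GARS1 (372 against 246 CPM), MARS1 (289 against 215 CPM) and TARS1 (355 against 294 CPM), while WARS1 (-0.63) was at 103 and 99.4 CPM. Secretory SEC, COP, SRP and SSR genes were lower in 8 of 41, collagens higher in 5 of 25 and lower in 2, and RAB genes lower in 7 of 48 and higher in 1, with adjusted p of 0.0828, 0.0828 and 0.137 with an estimated correlation.

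Of the tests that follow, those of the control gap, the splits, the USP17L members without unique sequence, the carriers as low as CTNNB1, the Wnt list by carriers and the 7-mers in USP17L were chosen after the results were seen. CTNNB1 mRNA was lower in all 3 USP17 libraries, and the controls' gap was 0.16 of their distance to them, which argues against 1 deviating control. A seed site shared by the 3 siRNAs may account for part or all of the fall: 1 7-mer of the CTNNB1 3' UTR, ATCACTC, marked lower genes in each USP17 library (-0.228, -0.191 and -0.135), the single one of 16163 to do so by 0.1 or more. Of its 884 carriers among 10800 genes searched 6.4% were as low as CTNNB1, against 1.1% of other genes, a gap partly built in because the 7-mer was picked for the fall of its carriers. CTNNB1 itself was at -0.78, -0.76 and -0.76 in siIDT, sino4 and siSMPLT, while the carriers' shift weakened from -0.228 to -0.135. Taking out the average effect of ATCACTC (-0.134) left CTNNB1 at -0.65 in place of -0.77. An average over carriers does not give the effect on 1 gene, so these values do not settle how much of the fall the site accounts for. ATCACTC occurs in 25 of 30 USP17L copies, which are near-identical and not independent, and 7.5% of the 7-mers tested occur in as many, while TCACTCA, of rank 1, 2 and 2 in the siIDT, sino4 and siSMPLT libraries, occurs in 0 of 30, TCACTCT, of rank 5, 3 and 3 and also in the CTNNB1 3' UTR, in 30 and GTGTGCC in 28. ATCACTC, TCACTCA and TCACTCT share the bases TCACTC, so their shifts and copy counts are not separate signals and may reflect the same site. The absence of TCACTCA from the copies therefore does not count against a site matched to USP17L. Loss of USP17 stays open as a cause too, and is untested here because the family had no reads.

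Wnt targets were lower as a list by camera at the preset correlation (adjusted p 6.45e-06), but the list did not pass with an estimated correlation (adjusted p 0.411) or by fry (0.0544). The 10 members that hold any of the 6 7-mers that marked lower genes in a USP17 library had a median log2 fold change of -0.71 and the other 12 of -0.13 (exact permutation p 0.0422 for the median and 0.00332 for the mean, one-sided, not matched for 3' UTR length), and those 12 did not pass camera (adjusted p 0.15; 0.705 with an estimated correlation). The same 6 were picked without the list's genes, but since they were picked for the fall of their carriers, some of this difference is built in, and it does not show direct sites to be the cause. For ATCACTC alone, leaving out its 4 carriers moved the list's mean from -0.46 to -0.28 and its median from -0.35 to -0.28. The camera adjusted p was then 0.000499, or 0.43 with an estimated correlation. The same permutation test gave these 4 carriers an exact p of 0.293 for the median and 0.0171 for the mean. FGF20 (-3.10) and PROX1 (-1.39) were the lowest of them. FGF20 was near the detection limit, at a mean of 0.144 CPM in the USP17 libraries against 1.264 CPM in the controls. In siSMPLT it was at 0.063 CPM, below the 0.0946 CPM that a count of 0 allows there. With the stricter filter the mean of the whole list was -0.326. The called targets searched kept 99.2% of their median fold after the average effect of ATCACTC was removed, but 83.9% would be kept if every target held it, so this value decides nothing, and direct sites and a fall that follows from lower CTNNB1, whatever lowered that, cannot be told apart for the list.

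GC content and length explained 1.0% of the variance of fold changes, against their being the source of the 1710 calls. Of 10 splits 1 called as many, the real one, and the highest other called 0, but 10 splits are too few for a share under 0.05. Every other split also mixes the groups, so any difference between them, whatever its cause, lowers its calls.

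The absence of USP17L reads was weighed against reads lost because copies are near-identical. That is argued against for 3 members with unique 50-mers, USP17L7 (64.1%), USP17L10 (45.6%) and USP17L2 (35.4%). It is argued against for 6 more, USP17L1, USP17L3, USP17L4, USP17L8, USP17L13 and USP17L14P, with 23.0% to 54.8% of their 50-mers in at most 4 copies: they had 0 RSEM expected counts, while RSEM gave reads to 5 genes without any uniquely counted read whose every 50-mer lies in 4 or more annotated loci, 4 of them copies of a ribosomal RNA. In the other 21 members the median share of such 50-mers was 3.5%, and the authors' limit on multi-mapping is not given in the sources used here, so silence and loss of reads cannot be told apart.

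In siL2 against the USP17 libraries, carriers of another 7-mer, GATCATC (725 genes), were lower than other genes by 0.221 on the log2 scale. This 7-mer occurs in 28 of 30 USP17L copies, as 6.1% of the 7-mers tested do in at least 28, and it overlaps ATCACTC there, starting at base 867 of the USP17L2 transcript where ATCACTC starts at base 871. The siRNA sequences are not given in the sources used here, so that siL2 leaves USP17 unaffected rests on its label alone, and a fold against the controls is a fold relative to siL2 as well. Without siL2, CTNNB1 was at -0.71 and 2430 genes passed. Against siNT alone, ATCACTC carriers were shifted by -0.24, -0.203 and -0.148 in the siIDT, sino4 and siSMPLT libraries and by -0.025 in siL2. In siNT the 7-mer ranked first, GCACTTT, had a shift of -0.052.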
